A study of Mus musculus with 26 samples.

How the data were processed

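Gene expression was measured in single cells of ovaries from mouse fetuses, in 26 libraries that span embryonic days E11.5 to E18.5. Per the labels' protocols, the mice carried the BVSC reporters, Blimp1-mVenus and Stella-ECFP, which mark germ cells. Blimp1 is the product of Prdm1 and Stella that of Dppa3. Gonads of several embryos were combined per stage, dissociated with trypsin and sorted by fluorescence. Single cells were then picked by mouth pipette, and their polyadenylated RNA was copied with cell barcodes and molecular identifiers by a modified STRT-seq protocol that enriches 3' ends.

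The deposited values are raw counts of unique molecular identifiers (UMIs) per gene and cell. Per the submitters' processing notes, the tools were CASAVA 1.8, UMI-tools, STAR, featureCounts and Subread, and the genome build was mm10. The roles of these tools, the gene annotation, the strand setting and the filters on cells and genes are not given in the sources used here. The deposited cell table gives for each cell its stage, library, replicate (R1 or R2), sort gate (BVSC, BV or Negative), total UMI count and number of genes detected. It names no cell types, so cells were classed by clusters and the markers listed beforehand for that case. Libraries carry the numbers 1 to 26 here, and the cell table's R1 and R2 can each span several libraries of a stage.

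The count table read here ended within a line of chromosome 8. Its 16344 complete genes lie on chromosomes 1 to 7, 10 and X and on the start of chromosome 8, up to Fnta (8:25998722-26015650). They hold a median of 51.2% of a cell's deposited UMI total (range 40.1% to 56.4%). Genes on the other chromosomes, among them Pou5f1, Ddx4, Dazl, Foxl2, Rec8 and Dmc1, were not analysed here. Positions came from GENCODE annotation of the GRCm38 (mm10) build: 16252 genes matched by symbol, 55 by an older symbol and 37 not at all. A total of 2248 genes (13.8%) had no UMI in any cell.

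All 1881 cells were kept. Counts of 11113 genes seen in at least 10 cells were scaled to 10000 per cell and log-transformed, and the 2000 most variable genes gave 30 principal components, a graph of 15 neighbours and Leiden clusters at resolution 1.0 (Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2). A cluster was classed as germ or somatic from the mean level of germ identity and early gonadal somatic markers, each as a percent of the highest cluster. Germ clusters reached at least 30% for the first and stayed below 15% for the second. Somatic clusters reached at least 30% for the second and stayed below 30% for the first. A cluster with at least 30% for the first and 15% for the second was called mixed. These limits were chosen after seeing the data. A somatic or other cluster took the name of a cell type with "-like" only if at least 3 markers of that type exceeded 2 times their mean in all other cells plus 5 CPM. No doublet caller was run on these hand-picked cells, and doublets are weighed in the closing section for the cluster with markers of both classes.

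UMI counts were summed per library, stage and class into pools of at least 5 cells. This gave 19 germ pools (1275 cells, 5 to 94 per pool, 1501161 to 27202730 UMIs) and 18 somatic pools (501 cells, 6 to 45 per pool, 720031 to 13027037 UMIs). CPM values were scaled by the deposited UMI totals of the pool's cells, so they refer to all genes and not to the part of the table read here. Libraries served as replicates. The labels do not say whether libraries of a stage came from separate animals, so p-values measure the spread between libraries, which may be technical.

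Counts were tested with edgeR's quasi-likelihood test (R 4.3.3, edgeR 4.0.16) with TMM scaling, filterByExpr and Benjamini-Hochberg adjustment at 0.05. Standard errors of log2 fold changes are the absolute fold change divided by the square root of the test's F. All germ pools shared a fit with a mean per stage. Its contrasts were E14.5 against E11.5, E16.5 against E14.5, E18.5 against E16.5 and each successive pair of stages. Germ and somatic pools were compared with stage as a covariate. A separate fit of the somatic pools gave E18.5 against E11.5, and a fit of all pools gave the difference of that stage effect between the classes. Where all pools of a group held 0 counts, folds are given as lower bounds from 3 counts over the group. With 1 to 3 counts the ratio has an exact 95% Poisson interval. Both cover counting error only.

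Gene lists were tested with limma's camera (3.58.1) on log2 CPM (prior count 2) at a preset correlation of 0.01, with adjustment over the lists that had at least 5 tested members. The 29 lists covered primordial germ cell pluripotency, germ identity, retinoic acid response and meiotic initiation, BMP signalling, synaptonemal complex and cohesin, meiotic recombination, S phase, G2 and M phase, oocyte and follicle genes, piRNA and transposon defence, DNA methylation, the male germ pathway, apoptosis and checkpoint, oxidative phosphorylation, glycolysis, immediate early genes that respond to dissociation, X inactivation, imprinted genes, steroidogenesis, and markers of early gonadal somatic cells, pregranulosa cells, surface epithelium, stroma, endothelium, perivascular cells, macrophages, erythroid cells, mesonephric epithelium and Sertoli cells. In all, 24 lists reached 5 tested members in some comparison.

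Genes were named by a fixed rule: per comparison, the 6 highest and the 6 lowest log2 fold changes among genes with adjusted p under 0.05, at least 50 CPM in the higher group and no overlap between the pools compared, leaving out predicted, ribosomal and mitochondrial gene symbols. Up to 4 tested members with the smallest p per list, and Xist, Stra8, Prdm1 and Dppa3, were named in addition. A few genes that the rule names are not reported here. The design, the gene lists, the naming rule and most alternatives were chosen before the data were examined. Of the genes in the table of named genes, 59 have exons that overlap another gene, whose reads cannot be told apart where the strand was not used. Members of the Rhox, Speer and Wfdc families share similar copies, so their counts are uncertain.

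The X-to-autosome ratio is the mean CPM of 476 X-linked genes over that of 5785 autosomal genes with a mean of at least 5 CPM, tested with two-sided permutation tests (scipy 1.17.1, numpy 2.4.6), exact where a group had under 10 pools and with 100000 resamples otherwise. Shares of cells have exact 95% binomial intervals.

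Before use, the tests were run on counts simulated from each gene's mean and fitted dispersion and the pools' sizes, with 200 changed genes per comparison. At 4-fold, the share recovered was 80% for germ against somatic pools, 45%, 39% and 32% for the first, middle and last germ windows, 13% for the somatic stages and 8% for the difference of stage effects. At 2-fold it was 49%, 8%, 9%, 1%, 1% and 0%. Unchanged genes made up 3.64% to 6.67% of the calls, and 20% for the difference of stage effects. The simulated pools were drawn independently and few genes were changed. These shares may therefore not carry over to comparisons that call many more genes or hold pools of the same library. Alternatives were DESeq2 (1.42.0), upper-quartile scaling, no filter on low counts, 10 or 1 cells as the pool minimum, removal of cells with fewer UMIs than the median of their stage and class divided by 3, pools thinned to the smallest total, the batch digits of the library names as a covariate, a replicate block, camera with an estimated correlation, fry, and each library left out in turn. Added after seeing the data were classes by sort gate, cells whose gate and cluster gave the same class, libraries merged by deposited replicate, totals of the table read here, removal of a germ cluster of low UMI counts, subtraction of germ transcripts from somatic pools, somatic pools with few germ cells in the library, the stroma-like cluster alone, stage and replicate as a block, and X-linked genes without multicopy families. The X-to-autosome ratio was also taken with a minimum of 10 CPM and as a median over genes, and each library was left out in turn.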

Results

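The series holds 1881 single cells of female mouse gonads, in 26 libraries from 8 stages, E11.5 to E18.5, with day E0.5 as the day of the vaginal plug. Female germ cells enter meiosis within this span and begin to form primordial follicles near birth. The sort gate was BVSC for 1302 cells, in which both germ cell reporters were read, Negative for 529 cells and BV for 50 cells. E11.5 had 184 cells, E12.5 had 189, E13.5 had 188, E14.5 had 465, E15.5 had 246, E16.5 had 280, E17.5 had 188 and E18.5 had 141. A cell had a median of 214706 UMIs (range 10016 to 948642) and 8147 detected genes (range 2438 to 12510). Libraries held 2 to 96 cells and 32782 to 29296017 UMIs. The median UMI count per cell ranged from 167672 at E16.5 to 268697 at E13.5.

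The cells fell into 15 clusters, of which 9 were germ-like by their markers and held 1277 cells. The germ clusters followed the stages. Cluster 7, led by Lefty2, L1td1 and Sox2, held 84.8% of the germ cells of E11.5. Cluster 2, in which the pluripotency gene Nanog and Gdf3 stood out, held 69% of those of E12.5. Cluster 6, led by the meiotic gatekeeper Stra8, held 39.1% of the germ cells of E14.5. Cluster 5, led by Lypd4, M1ap and Dmrtc2, held 45.4% at E15.5, cluster 3 (Ccnb3, Morn5, Gc) 56.4% at E16.5, and cluster 8, with the oocyte transcription factors Lhx8, Nobox and Sohlh1, 82.1% at E18.5. Cluster 10 had Spo11 among its leading genes and held 36.2% at E15.5, but 11.1% without library 16. Cluster 11 was also germ-like but had a low median of 101078 UMIs.

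Somatic clusters held 512 cells. Cluster 9 was stroma-like (127 cells; Tcf21, Dcn, Pdgfra), and cluster 14 was like surface epithelium or mesothelium (61 cells; Upk3b). Clusters 1 (243 cells) and 12 (81 cells) scored highest for pregranulosa markers. Of 11 such markers, 9 in cluster 1 and 8 in cluster 12 passed the limit for cluster names, although none was among their 10 leading genes. Cluster 12 had the mesonephric gene Pax8 among its 10. By the limit both clusters would be called pregranulosa-like, but their type is left open here. Cluster 15, with 20 cells, was like macrophages or other immune cells, and cluster 13, with 72 cells, showed markers of both classes; neither entered the comparisons. Of the 1302 cells in the BVSC gate, 1229 (94.4%) were germ-like, and of the 529 Negative cells 492 (93.01%) were somatic. Germ-like cells made up 71.4% of the 1789 cells in the germ and somatic classes (exact 95% binomial interval 69.2% to 73.5%), a share set by the sorting.

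Germ and somatic cells of the fetal ovary differ in the programs that keep germ cell identity, silence transposons and prepare meiosis. The comparison of the classes asks which transcripts set germ cells apart on average over the stages. Among 9745 genes tested in 19 germ and 18 somatic pools, 3618 were higher and 2784 lower in germ pools. With library as a replicate block, where a library held both classes, 4884 genes differed (2911 higher, 1973 lower; 12 against 12 pools). With classes taken from the sort gate alone, an alternative chosen after seeing the data, 6310 differed, of which 5965 were shared. The median log2 fold change of all tested genes was 0.24, against 0.21 with upper-quartile scaling, 0.08 with DESeq2 and -0.01 with thinned pools. Small differences thus depend on the processing.

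In the main fit Zfp936 (7:43114229-43192109) was highest by fold, at a log2 fold change of 5.45 ± 0.33 (SE, adjusted p = 2.8e-17). It had 57.9 ± 24.8 CPM (SD, n = 19) in germ and 1.65 ± 1.62 CPM (n = 18) in somatic pools. Tdrd12, which acts in the piRNA pathway, followed at 5.25. The X-linked Rhox2e, Rhox2c, Rhox2b and Trap1a were higher by 5.23, 5.22, 5.10 and 5.05 on the log2 scale. Tshz2 was lowest at -7.20 ± 0.42, with 1.60 CPM in germ and 176 CPM in somatic pools. C1qtnf7 (-7.07), AC167229.1 (-7.03), Gucy1a1 (-6.97), the long noncoding RNA Rmst (-6.96) and the adhesion gene Cntn4 (-6.88) were the next lowest. None of these 12 calls was lost in 17 alternatives, but the size and order of the higher folds changed. The log2 fold change ranged from 4.42 to 13.12 for Rhox2b and from 4.27 to 12.53 for Trap1a. It ranged from 4.53 to 10.93 for Tdrd12 and from 4.89 to 8.36 for Zfp936. Stra8 was higher by 4.61 ± 0.78. The genes behind the sort reporters, Dppa3 (3.62 ± 0.57) and Prdm1 (4.40 ± 0.45), were also higher. Cells were sorted on these reporters and Dppa3 was a marker used to class them, so both results were partly set in advance. Xist, the RNA that coats the inactive X chromosome (X:103460366-103483254), was at 4.54 ± 4.21 CPM in germ and 162 ± 56.8 CPM in somatic pools, a log2 fold change of -5.36 ± 0.36 (adjusted p = 9e-15). Its exons overlap those of the antisense gene Tsix.

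Germ programs stood out as lists. Primordial germ cell pluripotency genes were higher in 11 of 12 tested members, among them Tfap2c (5.39), Sox2 (5.49) and Sall4 (4.93), with 11 adjusted over the list alone (camera adjusted p = 0.00027, and adjusted p = 0.18 with an estimated correlation). All 8 synaptonemal and cohesin members were higher, among them Hormad1, Stag3 and Rad21l (8 adjusted over the list alone; 6.6e-05, and adjusted p = 0.151 with an estimated correlation). The 9 recombination members, such as Spo11 and Rnf212, were higher too (9 adjusted over the list alone; 9.5e-05, and adjusted p = 0.116 with an estimated correlation). The same held for the 9 piRNA members, with Asz1 and Mael (9 adjusted over the list alone; 4.2e-05, and adjusted p = 0.0559 with an estimated correlation). Genes of G2 and M phase, such as Bub1 and Cenpf, were higher in 7 of 12 (8 adjusted over the list alone; 0.0163, and adjusted p = 0.484 with an estimated correlation). Germ identity genes were higher in 7 of 7 (7 adjusted over the list alone; 0.00027, and adjusted p = 0.0534 with an estimated correlation), and early gonadal somatic genes such as Wt1 and Nr5a1 were lower in 5 of 6 (5 adjusted over the list alone; 0.00014, and 0.0138). Both of these lists had been used to class the cells. Their members Mael, Sycp3, Dppa3 and Tcf21 also belong to the piRNA, synaptonemal, pluripotency and stroma lists. All classes came from clusters of the same counts, so the p-values of every list in this comparison are not independent of the classes.

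Markers of somatic lineages were lower in germ pools, as were glycolysis and imprinted genes. Stroma genes, such as Col1a2 and Pdgfra, were lower in 12 of 12 (12 adjusted over the list alone; 2e-07, and adjusted p = 0.0559 with an estimated correlation), and pregranulosa genes, such as Kitl and Rspo1, in 10 of 11 (10 adjusted over the list alone; 2.7e-08, and 0.004). Imprinted genes, with Mest and H19, were lower in 12 of 15 (13 adjusted over the list alone; 2.7e-08, and 0.00046). Glycolysis genes were lower in 11 of 13 (11 adjusted over the list alone; 6.6e-05, and adjusted p = 0.272 with an estimated correlation). Ldha had 80.7 CPM in germ and 744 CPM in somatic pools. Immediate early genes that respond to dissociation, with Jun and Btg2, were lower in 5 of 5 (5 adjusted over the list alone; 2.7e-06, and 0.0485). Steroidogenesis genes were lower in 4 of 6 (4 adjusted over the list alone; 0.0404, and adjusted p = 0.0924 with an estimated correlation).

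The camera test made no call for the other lists. Oocyte and follicle genes were higher in 12 and lower in 2 of 18 members (12 and 2 adjusted over the list alone; adjusted p = 0.0819) and S phase genes higher in 7 of 10 (7; 0.109). BMP signalling genes were higher in 1 and lower in 4 of 5 (1 and 4; 0.164), DNA methylation genes lower in 3 of 7 (2; 0.164) and endothelial markers lower in 3 of 8 (3; 0.421). Male germ pathway genes were higher in 2 of 5 (2; 0.501), and apoptosis genes higher in 3 and lower in 3 of 12 (3 and 3; 0.57). Retinoic acid and meiotic initiation genes were higher in 3 and lower in 2 of 7 (3 and 2; 0.57), with a median of 0.23, a mean of -0.05 and a test direction of down. Oxidative phosphorylation genes were higher in 3 and lower in 1 of 7 (3 and 1; 0.798), and macrophage markers higher in 2 of 8 (1; 0.819). Lists with fewer than 5 tested members had no camera test. Jpx, Rlim and Xist of the 4 tested X inactivation genes were lower, as were Amh, Cst9 and Ptgds of the 4 Sertoli genes, 3 of 4 surface epithelium markers, 1 of 2 perivascular markers (2 adjusted over the list alone) and the mesonephric gene Pax8. The 4 erythroid markers had a median log2 fold change of -0.50 and were not called.

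Female germ cells start meiosis between E11.5 and E14.5. Stra8, which is needed for meiotic initiation, had 0 counts at E11.5 and 701 ± 120 CPM (SD, n = 4) at E14.5. The Nodal pathway target Lefty2 was among the transcripts that fell, and the synaptonemal complex genes rose as a list. Of 10033 genes tested, 827 rose and 532 fell between E11.5 (2 pools) and E14.5 (4 pools). With libraries merged by deposited replicate, chosen after seeing the data, 762 rose and 296 fell. A total of 466 genes changed without library 7 and 669 without library 1, each of which leaves 1 pool at E11.5 that is assumed to vary like the other stages.

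Stra8 (6:34920163-34939344) was at least 8909-fold higher at E14.5 (adjusted p = 0.0014), and Lypd4 (7:24864620-24869941), with 81.1 ± 5.59 CPM, was at least 1031-fold higher (8.9e-05). Figla, a transcription factor of oocytes, had 1 count at E11.5 and 92.8 ± 8.82 CPM at E14.5, a ratio of 3539 (interval 635 to 1.4e+05; adjusted p = 8.2e-07). Dmrtc2 rose by 6.73 ± 0.44 (172 ± 26.3 against 1.38 ± 0.12 CPM), Taf7l by 6.58 ± 0.61 and Ccnd1, whose exons overlap Lto1, by 6.73 ± 1.08 on the log2 scale. Platr10 fell by 6.06 ± 0.87, Fblim1 by 3.83 ± 0.52 and Map7d3 by 3.42 ± 0.76 on the log2 scale, and none of these 9 calls was lost in 19 alternatives. Lefty2 fell by 6.50 ± 1.48 on the log2 scale (0.775 ± 1.40 against 58.95 ± 52.6 CPM; adjusted p = 0.0065), but the adjusted p was 0.102 without library 7 and 0.056 with libraries merged by replicate, the 2 highest of its 19 alternatives. Gtsf1l fell by 3.37 ± 1.00 on the log2 scale (adjusted p = 0.0387), and lost the call without library 1 (0.115), 4 (0.0942), 5 (0.0551), 7 (0.273), 12 (0.106) or 14 (0.0911), with the batch covariate, with merged replicates and in both settings that use the sort gate, with 0.273 the highest of 18 alternatives. Prdm1 had 26.8 CPM at E14.5 and 78.8 CPM at E11.5 (adjusted p = 0.0486), and 13 of its 19 alternatives lost the call, among them without library 1 (0.19), 4 (0.122), 5 (0.084), 7 (0.209) or 14 (0.102). Dppa3 (582 CPM at E14.5 and 842 CPM at E11.5; adjusted p = 0.711) and Xist (log2 fold change -0.59; adjusted p = 0.739) did not pass the test.

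Meiotic programs rose in this window. All 8 synaptonemal and cohesin members rose (8 adjusted over the list alone; camera adjusted p = 6.3e-12, and 0.00049 with an estimated correlation). Sycp1, which forms the transverse filaments of the synaptonemal complex, went from 21.2 ± 10.3 to 562 ± 34.3 CPM (log2 fold change 4.54 ± 0.27). Recombination genes rose in 7 of 9 (7 adjusted over the list alone; 3.7e-07, and 0.0141), with Hfm1 at 3.01 and Tex11 at 2.90. Spo11, which makes the DNA breaks of meiosis, rose by 3.05. Germ identity genes rose in 4 of 7 (4 adjusted over the list alone; 0.0019, and 0.0214), with Mael at 3.18 and Tex101 at 5.16. The piRNA genes rose in 4 of 9 (5 adjusted over the list alone; 0.0019, and 0.0214), with Gpat2 at 2.31. The retinoic acid and meiotic initiation list rose with Stra8 and Gm4969 (2 of 7; 3 adjusted over the list alone; 0.015, and adjusted p = 0.0586 with an estimated correlation).

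The lists of glycolysis, pluripotency, the male germ pathway and the cell cycle fell between E11.5 and E14.5, and each of these camera calls was lost with an estimated correlation. Without library 7, 0 genes of each of these 5 lists were called. Of the pluripotency genes 0 were also called without library 1, 4, 5 or 14 and 1 without 12. Of the S phase genes 0 fell without library 1 and 1 without 12 or 14, and of the G2 and M phase genes 1 fell without 4 or 14. Glycolysis genes fell in 6 of 13 (8 adjusted over the list alone; 3.1e-05, and adjusted p = 0.242 with an estimated correlation). Pluripotency genes fell in 2 of 12 (2 adjusted over the list alone; 0.0191, and adjusted p = 0.509 with an estimated correlation), while Nanog had 41.9 CPM at E14.5 and 203 CPM at E11.5 (adjusted p = 0.126). Male germ pathway genes fell in 3 of 6 (4 adjusted over the list alone; 0.0191, and adjusted p = 0.509 with an estimated correlation). S phase genes fell in 2 and rose in 1 of 10 (6 and 1 adjusted over the list alone; 0.0412, and adjusted p = 0.509 with an estimated correlation). Genes of G2 and M phase fell in 2 of 12 (2 adjusted over the list alone; 0.0497, and adjusted p = 0.509 with an estimated correlation). Markers of red blood cells were lower in the same window, by a median of 4.508 on the log2 scale over 4 genes (0 called, 3 adjusted over the list alone), with Hbb-y at 3.28 CPM at E14.5 and 172 CPM at E11.5 (adjusted p = 0.0869).

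**Figure D1:**
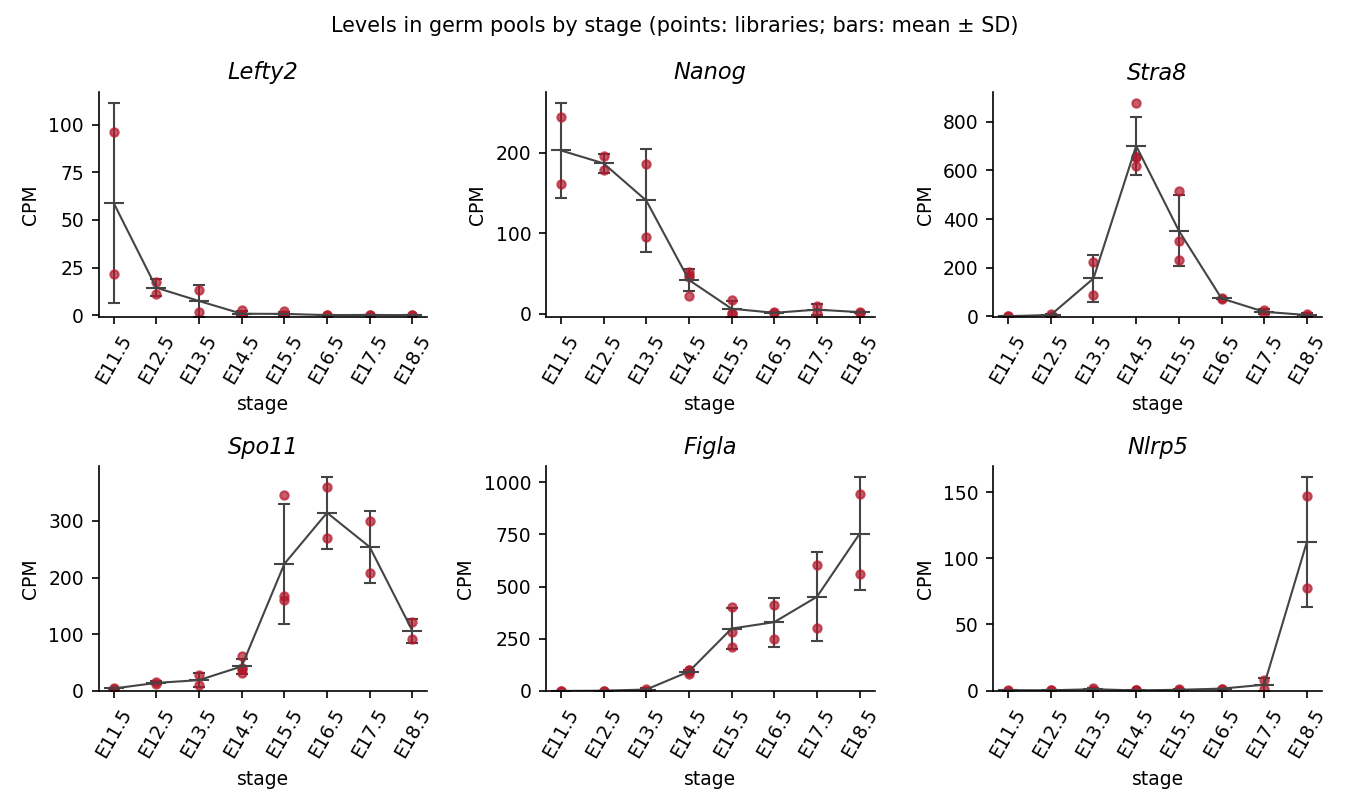
CPM of Lefty2, Nanog, Stra8, Spo11, Figla and Nlrp5 in each germ pool (points) by embryonic day, with the mean and SD per stage. Mean Stra8 was 701 CPM at E14.5 and 4.94 CPM at E18.5, and mean Figla was 753.5 CPM at E18.5.

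Between E14.5 and E16.5 germ cells pass through meiotic prophase. Tfap2c, a regulator of primordial germ cells, was nearly lost, and Mcm7, a replication gene, and Gapdh of glycolysis fell with it. Spo11 and Sycp1 rose further. Of 10033 genes, 810 rose and 765 fell (2 pools at E16.5, 4 at E14.5). The number was 473 without library 22 and 548 without library 20, which each leave 1 pool at E16.5 that is assumed to vary like the other stages. Among genes that rose in the first window 181 rose again, where 66.8 would be shared if the calls were independent, and 146 fell in both windows against 40.6. The windows share the pools of E14.5, which favours opposite directions by chance.

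Speer4a rose by 9.58 ± 1.10 (85.5 ± 45.6 against 0.116 CPM; adjusted p = 5e-05), Gc by 5.28 ± 0.65 (404 ± 19.7 against 10.2 CPM), Tmc2 by 5.07 ± 0.64 and Morn5 by 4.85 ± 0.94 on the log2 scale. Tfap2c fell by 7.53 ± 1.11 on the log2 scale (0.377 against 70.7 CPM; adjusted p = 0.00039). None of these 5 calls was lost in its alternatives. Phlda2, an imprinted gene (7:143501545-143503150), fell by 9.02 ± 1.77 on the log2 scale, from 438.5 ± 53.01 to 0.850 ± 0.150 CPM (adjusted p = 0.0059, and 0.0846 without library 20 and 0.0822 without library 22, the highest of 18 alternatives). On the log2 scale, Sct fell by 6.72 (adjusted p = 0.0895 without library 20, 0.109 without library 22) and Zfp462 had a fold change of -6.365 (0.0618 without library 22). Gstm3 fell by 6.52 on the log2 scale (0.0506 without library 5, 0.135 without 20, 0.215 without 22). Sohlh1, an oocyte transcription factor, rose by 4.36 ± 1.32 (adjusted p = 0.0437). It lost the call without library 4 (0.0863), 5 (0.102), 12 (0.0789), 14 (0.103), 20 (0.0962) or 22 (0.326), with 1 cell as the pool minimum and with merged replicates. Prdm1 fell by 3.01 ± 0.73 on the log2 scale (adjusted p = 0.008, and 0.054 without library 22). Stra8 had 73.3 CPM at E16.5 and 701 CPM at E14.5 (adjusted p = 0.0744), Dppa3 29.3 and 582 CPM (0.0707), and Xist a log2 fold change of 1.70 (0.253).

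Glycolysis genes fell in 10 of 13 (13 adjusted over the list alone; camera adjusted p = 1.4e-09, and adjusted p = 0.11 with an estimated correlation), with Gapdh at 42.9 CPM at E16.5 and 322 CPM at E14.5. Pluripotency genes fell in 10 of 12 (11 adjusted over the list alone; 1.2e-08, and adjusted p = 0.11 with an estimated correlation), with Ifitm3 at -4.67. S phase genes fell in 7 of 10 (8 adjusted over the list alone; 9.4e-07, and adjusted p = 0.11 with an estimated correlation), with the replication genes Mcm7 (-2.89) and Mcm2 (-2.70). Genes of G2 and M phase, such as Cdc20 (-1.82), fell in 7 of 12 (7 adjusted over the list alone; 0.00017, and adjusted p = 0.196 with an estimated correlation). Synaptonemal genes rose in 4 of 8 (5 adjusted over the list alone; 0.0051, and adjusted p = 0.11 with an estimated correlation), with Sycp1 at 1474 CPM. Recombination genes rose in 6 of 9 (7 adjusted over the list alone; 0.0092, and adjusted p = 0.172 with an estimated correlation). Spo11 went from 43.3 ± 12.6 to 314 ± 63.2 CPM (log2 fold change 2.88 ± 0.33). Oocyte genes rose in 5 and fell in 1 of 17 (6 and 2 adjusted over the list alone) without a camera call (0.426). Without library 22 the genes called were 6 of glycolysis, 3 of pluripotency (4 without library 20), 2 synaptonemal and 3 of recombination. Of the oocyte genes 1 rose and 0 fell without library 22, and 3 rose without library 4, 5, 12 or 20, with 2 that fell without library 4.

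From E16.5 to E18.5 oocytes near follicle formation, and this window had the fewest called genes. It compares 2 pools with 2, and the simulation recovered 32% of 4-fold changes here against 45% and 39% in the earlier windows. At 2-fold the shares were 1% against 8% and 9%. Lower power may thus account for part of the gap in calls, and how large a part was not tested. The maternal effect gene Nlrp5 rose as the 1 oocyte gene called over all genes, and the oocyte list passed camera only at the preset correlation (adjusted p = 2e-05, and adjusted p = 0.36 with an estimated correlation). M1ap, a meiotic gene, fell. Only 27 genes rose and 32 fell of 10033 (2 against 2 pools), where 1242 passed at an unadjusted p under 0.05. In the first and middle windows 2825 and 3028 passed at that unadjusted limit. These counts rest on single libraries: 3 genes changed without library 20, 13 without library 22, 11 without library 26 and 231 without library 6, of which 51 were among the 59. Each of these fits leaves 1 pool in a stage, assumed to vary like the other stages.

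M1ap (6:82946902-83030309) fell by 2.37 ± 0.28 on the log2 scale, from 318 ± 47.2 to 62.5 ± 8.33 CPM (adjusted p = 0.0002), with no call lost in 16 alternatives. Nlrp5 (7:23385889-23441922) rose by 6.31 ± 1.28, from 1.45 ± 0.04 to 112.5 ± 49.1 CPM (adjusted p = 0.0189, and 0.381 without library 20, 0.207 without 22 and 0.165 without 26). Vil1 rose by 6.27 on the log2 scale (adjusted p = 0.44 without library 20, 0.109 without 22, 0.124 without 26), Tesc by 5.13 (0.129, 0.168 and 0.0614 in the same order) and Phactr3 by 4.92 (0.369, 0.0526 and 0.0614). AU015836 rose by 4.70 on the log2 scale (0.0637 without library 6, 0.464 without 20, 0.0868 without 22, 0.155 without 26) and Mvp by 4.65 (0.446 without library 20, 0.381 without 22, 0.188 without 26). Mvp also lost the call with 10 cells as the pool minimum, with merged replicates and in both settings that use the sort gate. Cited1 fell by 2.38 on the log2 scale (0.0598 without library 20, 0.0657 without 26) and Nmb by 2.16 (0.211 without library 20). Ifitm1 fell by 2.22 on the log2 scale (0.199 without library 6, 0.511 without 20, 0.103 without 22, 0.191 without 26), Kcnq1ot1 by 2.18 (0.143 without library 20, 0.0526 without 22, 0.127 without 26) and Acss2 by 2.13 (0.0753 without library 6, 0.338 without 20, 0.111 without 26). Thinned pools also ended the calls of Ifitm1 and Kcnq1ot1, and for Ifitm1 so did merged replicates and the cells whose gate and cluster gave the same class. Exons of Vil1, Mvp, Kcnq1ot1, Nmb and Acss2 overlap Usp37, Pagr1b, Kcnq1, Sec11a and Gss. Dppa3 had 528 CPM at E18.5 and 29.3 CPM at E16.5 (adjusted p = 0.279), Stra8 4.94 and 73.3 CPM (0.223), Prdm1 a log2 fold change of 0.34 (0.907) and Xist one of 0.01 (1).

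Oocyte and follicle genes rose in 1 of 17 (6 adjusted over the list alone; camera adjusted p = 2e-05, and adjusted p = 0.36 with an estimated correlation). Lhx8 had 378 CPM at E18.5 and 56.8 CPM at E16.5 (adjusted p = 0.129) and Zp3, which codes for a zona pellucida protein, 5.86 and 0.0338 CPM (0.122). Synaptonemal genes had 1 member that fell, Stag3 (2 adjusted over the list alone; camera adjusted p = 0.0741), and its call was lost without library 20 (0.339), 22 (0.105) or 26 (0.221).

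Successive stages of germ cells were compared as well. The counts do not date the changes, since the steps differ in pools, and the 3 steps within the first window called 7, 13 and 196 genes where the window called 1359. From E14.5 to E15.5 (4 and 3 pools) 721 genes were higher and 592 lower, from E13.5 to E14.5 (2 and 4 pools) 173 and 23, and from E15.5 to E16.5 (3 and 2 pools) 17 and 70. The other 4 steps compare 2 pools with 2. From E11.5 to E12.5, 7 genes rose and, by edgeR, 0 fell (141 fell at an unadjusted p under 0.05, and 6 by DESeq2). From E12.5 to E13.5, 10 genes rose and 3 fell, named Gm364, Gm1140 and Gm14692, all under 2 CPM. From E16.5 to E17.5 edgeR called 0 genes, with 239 at an unadjusted p under 0.05 and 5 by DESeq2. From E17.5 to E18.5 Akap12 rose (62.5 ± 14.1 against 4.47 ± 3.85 CPM; n = 2 and 2; edgeR adjusted p = 0.0264) and M1ap fell (0.0399), and DESeq2 called 143. These 5 genes were named after their values were seen.

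**Figure D2:**
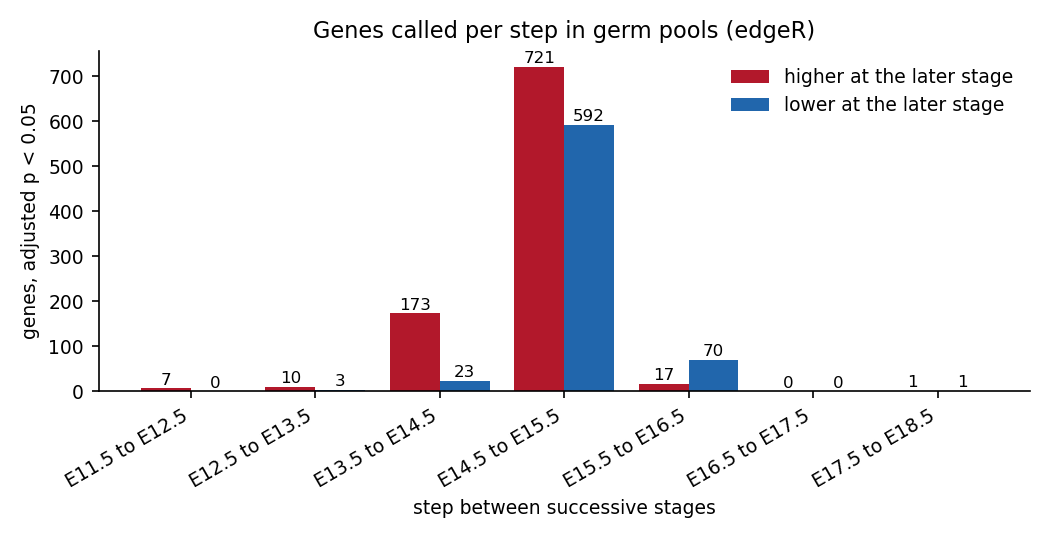
Number of genes higher and lower (adjusted p under 0.05) at each step between successive stages in germ pools. The step from E14.5 to E15.5 compares 4 with 3 pools (721 higher and 592 lower), and 4 of the other steps compare 2 with 2.

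The counts of steps depend on the libraries. For E14.5 to E15.5 they were 859 without library 4, 738 without 5, 838 without 12, 836 without 14, 461 without 16 and 1991 without 18, and 155 with the libraries merged by deposited replicate. For E13.5 to E14.5 they were 113 without library 4 and 37 without library 10. For E15.5 to E16.5 they were 350 without library 16, 36 without 17 (whose germ pool is 5 cells of the Negative gate), 6 without 20 and 3 without 22. For E12.5 to E13.5 they were 2 without library 3, 1 without 8, 5 without 9 and 20 without 10, and for E11.5 to E12.5 3 without library 7. For E16.5 to E17.5 1 gene was called without library 25. For E17.5 to E18.5 there were 68 without library 6, 16 without 24, 0 without 25 and 0 without 26. A fit with 1 pool left in a stage assumes that it varies like the other stages.

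Somatic cells of the gonad differentiate into pregranulosa, stromal and surface cells over the same days, so the comparison of E18.5 with E11.5 covers a mix of types. Of the somatic cells of E11.5, 53.2% were in the stroma-like cluster 9 (33.3% without library 7) and 44.7% in cluster 12. At E18.5, 38.5% were in cluster 1, 33.3% in cluster 14 (15% without library 6 and 52.6% without library 26) and 25.6% in cluster 9 (15.8% without library 26). No test was made of these shares. Of 8680 genes, 143 rose and 82 fell (2 against 3 pools). The total was 97 without library 26 and 135 without library 6, which each leave 1 pool at E18.5 that is assumed to vary like the other stages. Within the stroma-like cluster 75 genes changed, 23 of them shared.

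Fcgr2b, an Fc receptor (1:170958617-170976547), had 0 counts at E11.5 and 78.2 ± 8.26 CPM (SD, n = 2) at E18.5, at least 143.7-fold higher (adjusted p = 0.0014). Crygb had 3 counts at E11.5 and 182 ± 79.3 CPM, a ratio of 333.8 (interval 114.2 to 1619; adjusted p = 5.4e-07). Mael, a germ cell gene, rose by 6.89 ± 1.12 (129 ± 40.3 against 1.17 CPM). No alternative lost these 3 calls. Svs5 was at least 107.8-fold higher, and the ratios of Wfdc6a and Wfdc6b were 135.4 (interval 46.3 to 656.4) and 121.4 (41.5 to 588.7). These 3 calls were lost within the stroma-like cluster alone, as were those of Eps8, Spp1 and Lor, which fell. Eps8 had 1 count at E18.5 and was lower by a ratio of 261.7 (interval 46.97 to 1.03e+04; adjusted p = 0.0635 without library 26). Spp1 fell by 7.34 ± 1.49 on the log2 scale (0.132 without library 6, 0.122 without 26; the call was also lost with classes by sort gate) and Lor by 6.43 (0.0736 without library 6, 0.0503 without 26). Asb4 fell by 6.05 on the log2 scale (0.0632 without library 1, 0.0649 without 6, 0.105 without 7, 0.252 without 26) and Sphkap by 5.83 (0.0751 without library 1, 0.105 without 2, 0.173 without 6, 0.122 without 26). Asb4 also lost the call with the batch covariate, thinned pools or 1 cell as the pool minimum, and Sphkap with 1 or 10 cells as the minimum, merged replicates or subtracted germ transcripts. Xist had 156 CPM at E18.5 and 129.5 CPM at E11.5 (adjusted p = 0.923), Dppa3 a log2 fold change of 0.37 (0.916), Prdm1 an adjusted p of 0.561, and Stra8 1 count at E18.5 and 0 at E11.5.

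Germ cell lists moved in somatic pools as well, but the share of germ transcripts in these pools also differed between the stages. As a median over germ-list genes it was 12.07% and 13.16% of the germ level at E18.5. At E11.5 it was 7.919%, 2.676% and 6.16%. Changes of germ cell lists in somatic cells thus cannot be told apart from germ transcripts carried into the pools. Oocyte genes rose in 3 of 14 (6 adjusted over the list alone; camera adjusted p = 1e-05, and 0.0437 with an estimated correlation), among them Lhx8 at 36.3 CPM with 0 counts at E11.5 (adjusted p = 0.0366). Its call was lost without library 1 (0.0925), 2 (0.0717), 6 (0.0829), 7 (0.0895) or 26 (0.122), and the list had 0 called genes without 1, 2, 6 or 26 and 1 without 7. The piRNA genes rose in 1 of 9, Mael (1 adjusted over the list alone; 0.0024, and adjusted p = 0.373 with an estimated correlation). Germ identity genes rose in 1 of 7 (3 adjusted over the list alone; 0.0116, and adjusted p = 0.266 with an estimated correlation). Pluripotency genes fell as a list with 0 of 12 called by edgeR (4 adjusted over the list alone; 5.1e-07, and adjusted p = 0.103 with an estimated correlation), and synaptonemal genes rose with 0 of 7 called (1 adjusted over the list alone; 0.0043, and adjusted p = 0.512 with an estimated correlation). BMP signalling fell with Msx1 and with Bmp2, whose adjusted p was 0.115 without library 26 (2 of 5; 3 adjusted over the list alone; 0.0116, and adjusted p = 0.119 with an estimated correlation). Glycolysis fell with Gapdh and Ldhb (2 of 13; 3 adjusted over the list alone; 0.008, and adjusted p = 0.373 with an estimated correlation). The Gapdh call was lost without library 1 (0.138), 2 (0.0762), 6 (0.11) or 26 (0.287), and the Ldhb call without 6 (0.0642) or 26 (0.134). In addition, S phase genes fell with 0 of 10 called (0 adjusted over the list alone; 0.0387, and adjusted p = 0.563 with an estimated correlation). After germ transcripts were subtracted from the somatic pools, an alternative chosen after seeing the data, camera called 0 of 22 lists. The subtracted share was itself taken from genes of the pluripotency, germ identity, synaptonemal and oocyte lists. The loss of their calls was thus partly set in advance and is no independent evidence.

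**Figure D3:**
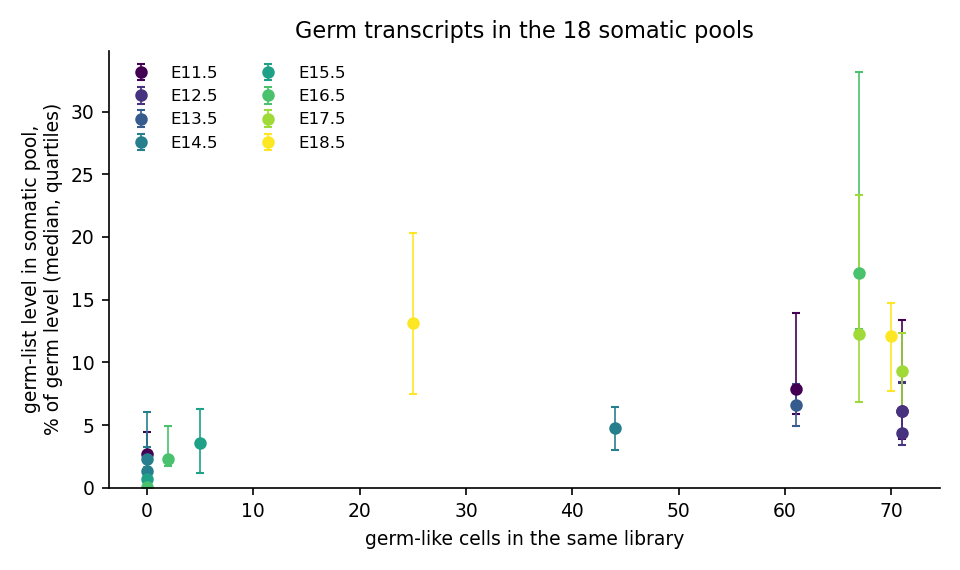
Level of germ-list transcripts in each somatic pool as a percent of the germ pools of the stage (median and quartiles over genes) against the number of germ cells in the same library. Pools from libraries with 25 or more germ cells lie between 4.35% and 17.1%, and those from libraries with 5 or fewer between 0.0566% and 3.58%. The pool at 17.1% is 6 cells of library 20, all from the BVSC gate.

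Germ and somatic cells can share changes that come with age, so the difference of their stage effects, E18.5 against E11.5, was tested directly. Of 11184 genes, 199 changed more upward in germ than in somatic pools and 452 more downward (4 germ and 5 somatic pools). The total was 363 without library 1, 365 without 6, 409 without 7 and 284 without 26, each of which leaves 1 germ pool at a stage, assumed to vary like the other groups. The share of upward genes was 30.6%, 41.5% with upper-quartile scaling and 49% with DESeq2, which moved the median of all genes from 0 to 0.21. With germ transcripts subtracted from the somatic pools, chosen after seeing the data, the share was 50.6% and the median 0.28. Camera then also called oocyte (adjusted p = 0.0016), recombination (0.0198) and synaptonemal genes (0.0282) upward, and male germ pathway genes downward (0.0115). The subtracted share was taken in part from the oocyte and synaptonemal lists. Glycolysis genes differed downward in 8 of 13 (11 adjusted over the list alone; camera adjusted p = 1.1e-07, and adjusted p = 0.315 with an estimated correlation), with Gapdh at -3.04 ± 0.46 and Hk2 at -4.76 ± 0.74. Pluripotency genes differed in 1 of 12, Ifitm3 at -8.76 ± 0.78 (1 adjusted over the list alone; 0.0033, and adjusted p = 0.789 with an estimated correlation). S phase genes differed in 3 of 10 (4 adjusted over the list alone; 0.0109, and adjusted p = 0.789 with an estimated correlation), with Mcm7 at -3.06 ± 0.59. The S phase count was 1 without any single library of 1, 2, 6, 7 and 26, and without library 6 the glycolysis count was 4 and the pluripotency count 2. The stage effects of Stra8 (adjusted p = 1), Xist (0.976), Dppa3 (0.896) and Prdm1 (0.657) were not shown to differ.

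Female germ cells reactivate their silent X chromosome as they enter meiosis, which can raise X-linked transcripts over autosomal ones. The X-to-autosome ratio in germ pools was 0.912 ± 0.0124 (SD, n = 2) at E11.5, 1.15 at E16.5 and 1.09 ± 0.0228 (n = 2) at E18.5. The mean of the somatic pools was 0.867 ± 0.0381 (n = 3) at E11.5 and 0.951 ± 0.0189 (n = 2) at E18.5, a difference that was not tested. The difference of E18.5 and E11.5 in germ pools was 0.176 (exact two-sided permutation p = 0.333, the smallest that 2 against 2 pools allow). Germ pools had a ratio of 1.07 ± 0.084 (n = 19) and somatic pools 0.922 ± 0.0367 (n = 18), a difference of 0.146 (two-sided permutation p = 2e-05, the smallest the resamples can give). Without the Rhox and other multicopy families, a choice made after seeing the data, the difference was 0.0793 (p = 0.00146). Neither stage nor library was a term of this test. It treated the pools as independent, although some libraries gave a pool to each class. The ratio covers only the chromosomes read here.

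**Figure D4:**
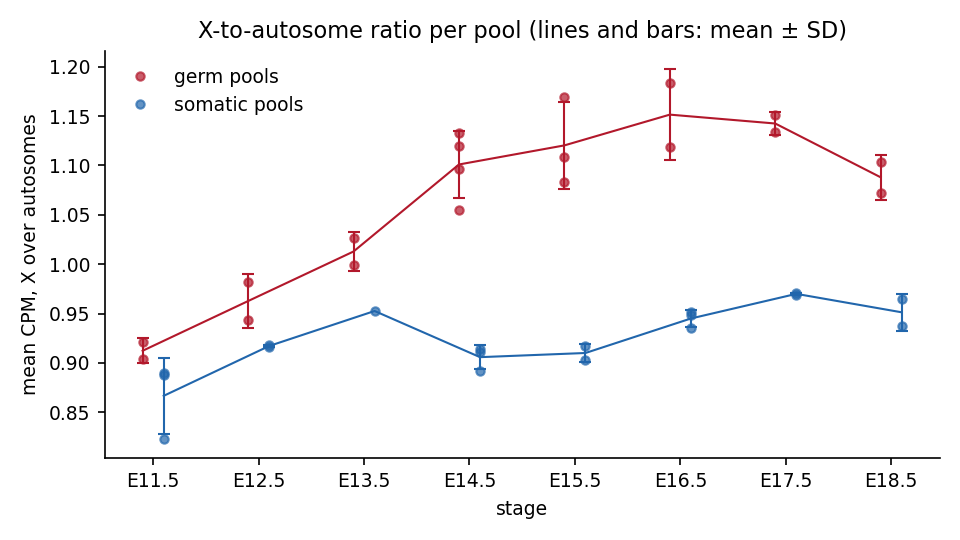
Ratio of the mean CPM of X-linked to autosomal genes in each germ and somatic pool by embryonic day, with means per stage. Germ pools average 0.912 at E11.5 and 1.15 at E16.5, and somatic stage means lie between 0.867 and 0.970.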

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

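Tests chosen only after the result was seen were the ratio of germ transcripts between libraries with many and few germ cells, the test of different points along the change at E15.5, the splits of sort-gate pools, and the UMI totals of the cells with markers of both classes.

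Somatic pools held germ-list transcripts at 4.35% to 17.1% of the germ level in libraries with 25 or more germ cells and at 0.0566% to 3.58% in libraries with 5 or fewer. Transcription in the somatic cells would give the same share in both kinds of library, but the share was higher with many germ cells by at least 2.064 times at E11.5, E14.5 and E16.5 (1 or 2 pools per kind), which argues against it as the whole source. At E16.5 the pool with many germ cells was 6 cells of library 20, all from the BVSC gate, so that stage carries little weight. The ratios at E11.5 and E14.5 were 2.302 and 2.064. A few germ cells or doublets among the somatic cells would leave the median cell low. It held 87.82% of its pool's mean, as a median over pools of libraries with 25 or more germ cells. In libraries with 0 germ cells it held 55.9% (library 2) to 99.14% (library 13). An even spread was thus also seen where no germ cells were present, so this value cannot decide. RNA of germ cells from the same library may contribute: the 1 germ pool of a library with many somatic cells had at least 2.103 times the somatic transcripts of the others at E13.5 (1 pool) and E14.5 (3 pools), too few to rest on alone. No biological explanation was tested beyond transcription in the somatic cells.

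Germ libraries of E15.5 stood apart. Along the change from E14.5 (0%) to E16.5 (100%), library 16 (R1) lay at 85.08%, library 17 (R1, 5 cells, all from the Negative gate) at 58.5% and library 18 (R2) at 37.49%. After thinning to the smallest total 100.5% of the gap was left. Thinning keeps the CPM of a deep pool about the same and does not alter depth per cell, so it does not decide on depth. The median UMI count per cell was 263624 in library 16 and 214706 in library 18. The share of somatic transcripts differed by 1.163 percentage points, beside a gap of 47.59. These percentages are on unlike scales, a share of CPM and a position on a log2 axis, so they do not decide on somatic cells or RNA. The median log2 difference of library 16 minus library 18 was -0.7121 over 765 genes that fell to E16.5 and 0.5252 over 810 genes that rose, but this test of cells at different points of the change runs on the genes that define it and decides nothing. Different points of the change, embryo age within the stage, depth, somatic cells or RNA and the choice of cells picked all remain open. No biological explanation was tested.

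Cluster 13, whose 72 cells showed markers of germ and somatic classes, entered no comparison; 39 of its cells were at E16.5, and 48 came from the BVSC gate, 4 from BV and 20 from Negative. Germ and somatic cells sequenced together would hold more UMIs. The median was 0.966 of that of the germ and somatic cells of the same libraries. At E16.5, however, the cluster had a median of 196157 UMIs, above the 158759 of germ and 177588 of somatic cells. At E14.5 (11 cells) it had 96426, below their 253867 and 208573. The stages went opposite ways, so the totals do not decide. For a blend of the profiles, fitted with a germ share of 40.4%, 22 genes lay above 2 times the highest cluster mean of E16.5 and the highest of 100 blended draws gave 0, but such draws lie near 0 by construction, so the count decides nothing. Cells sequenced together, a blend and a rare somatic type that carries germ transcripts all remain open, and no biological explanation was tested.

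The comparison of germ and somatic pools called 6402 genes. Of 100 splits of the pools, 1 gave as many, the real one, and the highest other gave 78, but the classes were made from the same counts, so these splits say nothing about chance. With classes by sort gate, which do not come from the counts, 6310 genes were called, and 1 of 100 splits gave as many, the real one, with 980 as the highest other. Chance can be excluded there only if the pools are independent, but some libraries give a pool to each class. With classes by cluster the deviations of such pools correlated over 0.1 in 9 of 11 pairs, some of which repeat a value by construction. With those classes and library as a block 4884 genes were called. The step from E14.5 to E15.5 called 1313 genes, which 1 of the 35 splits of the 7 pools gave, the real one, and the highest other gave 4. Chance can be excluded here, too, only if the 7 libraries are independent, but libraries 4, 5 and 12 share R1 of E14.5 as 16 and 17 share R1 of E15.5. Merged by deposited replicate, the step called 155 genes (2 against 2 pools).

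At E14.5 the germ pool of library 14 stood far from the others with Lefty2 at 2.87 CPM, and that of library 4 with Stra8 at 878.6 CPM. At E15.5 library 16 had a median of 263624 UMIs per cell, far from the other libraries of that stage. Such gaps arose in 3 of 34 groups tested, and chance gives about 1 in 20. The stage effect differed between germ and somatic pools for 651 genes, and for the lists of pluripotency (camera adjusted p = 0.003335), S phase (0.01091) and glycolysis (1.052e-07), each of which had an adjusted p above 0.3 with an estimated correlation. The 20 cells like macrophages or other immune cells, outside every comparison, had C1qb at 411.7 CPM, against 1.47 CPM in germ and 2.95 CPM in somatic pools.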

How the results depend on the processing

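Classes by sort gate, cells whose gate and cluster gave the same class, merged replicates, totals of the table read, removal of the germ cluster of low UMI counts, subtraction of germ transcripts, the stroma-like cluster alone, somatic pools with few germ cells, stage and replicate as a block and X-linked genes without multicopy families were chosen after seeing the data. The causes of the differences below were not tested.

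The germ against somatic count ranged from 4555 to 6805 over its alternatives and stayed within 1.5 times, as did the total of the middle window apart from single libraries. The directions of the middle window moved more. It had 810 genes higher and 765 lower, but 442 and 644 with merged replicates and 985 and 1114 with DESeq2. With DESeq2 the first window gave 2174 genes, the last 386, the somatic stages 643, the difference of stage effects 1146 and the successive stages 3236. Without the filter the last window gave 304, the somatic stages 463 and the successive stages 2743. With 1 cell as the pool minimum the last window gave 108, the somatic stages 27, the difference of stage effects 218 and the successive stages 1067, and with 10 cells the last window gave 115. Thinned pools gave 106 in the last window. Classes by sort gate gave 117 in the last window and 795 over the successive stages, where cells with the same class by both gave 1062 and merged replicates 275. The stroma-like cluster alone gave 75 for the somatic stages.

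With single libraries left out the first window ranged from 466 to 1154 genes, the middle from 473 to 1291, the last from 3 to 231, the somatic stages from 97 to 228, the difference of stage effects from 284 to 561 and the successive stages from 951 to 2351. The X-to-autosome difference between classes stayed between 0.140 and 0.154. The replicate block by library gave 4884 genes for germ against somatic pools and 786 for the difference of stage effects. In 9 of 11 pairs of pools from 1 library the correlation of their deviations was over 0.1 (-0.0454 to 0.422). At E12.5, E17.5 and E18.5 both pairs of a stage give the same value by construction (0.103, 0.266 and 0.321), so these pairs are not independent.

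With an estimated correlation camera called 4 lists for germ against somatic pools, 4 in the first window, 0 in the middle, 0 in the last, 1 for the somatic stages and 0 for the difference of stage effects. Fry called 20 lists for germ against somatic pools, 10 in the middle window and 5 in the last. After subtraction of germ transcripts, with a share taken from some of the tested lists, camera called 0 lists for the somatic stages. It then called 7 for the difference of stage effects.

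For the named genes, 9948 of 10743 values kept their direction and side of the threshold, 521 lost a call, 273 gained one and 1 changed sign: Ndufa4 in germ against somatic pools, at 0.00429 (adjusted p = 0.979) with somatic pools of few germ cells. DESeq2 gave no adjusted p in 36 cases, which are left out. The batch covariate was not run where the compared stages do not both span the batches, and the block by library not where each library holds 1 stage of 1 class. The simulation did not vary depth, and at 2-fold it recovered 1% of the changes in the last window (2 against 2 pools).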

Other observations

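Cell names at E13.5 to E16.5 carry a letter (P, C or D) whose meaning the labels do not give. Between the letters, tested within 10 libraries on 27 germ pools of 760 cells and 9272 genes, edgeR called 0 genes, with 286 at an unadjusted p under 0.05 and 0 by DESeq2.

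The BV gate held germ-like cells at E14.5. In library 4, 13 such cells had Dppa3 at 634.6 CPM, Stra8 at 938.5 CPM, Nanog at 19.44 CPM and Figla at 28.44 CPM, and 31 BVSC cells had 575.8, 859.2, 23.22 and 120.9 CPM. In library 5, 27 BV cells had 449.5, 841.9, 8.78 and 184.5 CPM in the same order, and 61 BVSC cells had 765.9, 566.7, 71.2 and 45.6 CPM, so Dppa3 and Figla went opposite ways in the 2 libraries. The difference between the gates was not tested. In library 4 all BV cells carried the letter P and all BVSC cells the letter D, so gate and letter cannot be told apart there.

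The 20 cells like macrophages or other immune cells had Fcer1g at 795.7 CPM, Tyrobp at 599.6 CPM, Lyz2 at 525.3 CPM and Ptprc at 129.3 CPM.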
